A study of Mus musculus with 200 samples.

How the data were processed

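The study measured the transcriptome of 200 single medullary thymic epithelial cells of female B6xNOD mice aged 5 weeks that carry a GFP reporter of Aire. Cells were sorted as CD45-negative, Ly51-negative, MHC class II-positive and GFP-positive, from Aire wild-type (WT) or Aire knockout (KO) mice, with high (GFPhi) or low (GFPlo) GFP. Per the submitters' protocol notes, tissue was digested with collagenase and dispase, single cells were lysed in 96-well plates by freeze-thaw, and RNA was copied with oligo-dT primers, made double stranded, transcribed in vitro with T7 polymerase and ligated to an adapter.

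The deposited table holds whole-number counts per gene and cell, which the authors gave without normalization. Per the submitters' processing notes, TopHat or TopHat2, Picard 1.79, SAMtools 0.1.19, HTSeq and the mouse genome mm10 were used. Those notes give no role or order for the tools, and they do not say whether molecular identifiers were collapsed. A cell's total exceeded the identifier count of the deposited metadata in 40 cells and exceeded its unique reads in 0 cells, so counts were treated as sequenced tags rather than as molecules. Per the file headers, the metadata also give flow cytometer intensity per well in arbitrary units and a sort date. Gene positions came from GENCODE release M21 on the same genome build (GRCm38, mm10), matched by gene name. Spt1, Igj, Epb4.9 and AC163677.1 have no placement under these names there.

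The table has 38406 genes, of which 16848 were at 0 in every cell. All 200 cells were used, with no filter on cells and no step for doublets, and 0 columns of values were left without a sample. There were 0 pairs of cells with identical counts. The 37 genes of the mitochondrial genome had 0 counts, so a mitochondrial share was not usable as a measure of cell quality. Totals per cell ran from 2429 to 370365 counts with a median of 29106.5. Cells came in 12 library pools, 6 per sort date, with 72 cells of the first date and 128 of the second, and with primers of a kind called ls in 153 cells and umi in 47.

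The labels name no animal, and replicate numbers only name cells, so each group counted as 1 sample and no test was made. The planned edgeR test over counts summed per animal was not run for this reason. Counts were summed over the cells of a group and divided by the group total to give levels per 1000000 counts. Levels carry exact Poisson and ratios exact conditional binomial (Clopper-Pearson) 95% intervals, and shares of cells carry exact binomial 95% intervals. These intervals treat each tag as an independent draw. They cover counting error of tags only, not copies made by amplification or differences between cells, animals or sort dates. If identifiers were not collapsed, they are too narrow for counts of molecules. Against a group at 0, a fold is stated as at least its value with the group set at 3 counts. Log2 ratios had 0.5 count added to each sum. TMM factors between group sums were made with edgeR 4.0.16 in R 4.3.3 and served as an alternative scaling. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

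The groups, results, alternatives and 40 gene lists were fixed before the data were examined. The lists comprise 10 of tissue antigens, markers of the sorted and of other cell types, cell states, and 18 gene families. Each was summed as 1 quantity, and the median log2 ratio of members with at least 10 counts was placed among 10000 random lists of the same size matched on mean level in 20 bins. That percentile describes these libraries and is no test. Where stated, medians cover members with at least 10 counts in the 2 groups compared, a choice made after the data were seen. In the comparisons other than KO against WT in GFPhi, the lists printed were chosen after their values were seen.

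Genes were named by a fixed rule. They had at least 20 counts over the 2 groups, counts in at least 5 cells of the higher group, at most 50% of that group's counts in 1 cell, and the same direction in the mean of per-cell levels. Gene models, pseudogenes, spike-ins and ribosomal protein genes were left out. Genes were ranked by the bound of the ratio interval nearest to 1, and the 12 highest and lowest of KO against WT in GFPhi and the 8 of each other comparison are given, except for 1 gene that is not reported here. Aire, Ins2, Fezf2, H2-Aa, Epcam, Krt5, Krt14 and Krt8 were named in advance. Of each list the members with most counts or extreme ratios were eligible, among them Csn2, which was not named in advance.

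Genes detected per cell were counted after each cell was thinned without replacement to 13300 counts, which leaves out 13 WT GFPhi, 10 WT GFPlo, 8 KO GFPhi and 9 KO GFPlo cells. Rare genes were the 8327 detected in 1 to 10% of the thinned cells. Alternatives were other depths and shares, each sort date alone, each pool left out, primer kinds, the 40 cells of lowest depth left out, the mean of per-cell levels, TMM scaling, a Mantel-Haenszel ratio over pools, and sums without the cell that held most counts of a gene or list in each group (top cells). Leaving out cells with more counts of leukocyte than of epithelial genes (leukocyte-marked cells) and leaving Csn2 out of its list were added after the data were seen.

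The calculations were tested on simulated data made from KO against WT in GFPhi with planted folds. Counts were Poisson draws from a shared mean profile, with no other differences between cells, pools or dates than cell totals. The coverage below therefore checks the calculation, not whether the intervals hold for the spread of real cells. For folds of 0.125, 0.25 and 0.5, each in 33 genes, 93.9%, 97.0% and 93.9% of intervals held the planted value. For folds of 2 and 4, each in 34 genes, 97.1% did, and for a fold of 8 in 33 genes 90.9% did. Of 13329 unchanged genes, 95.3% of intervals held 1 and 4.70% excluded it. A list of 99 lowered genes lay at percentile 0, one of 101 raised genes at 100 and one of 100 unchanged genes at 6.89.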

Results

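Transcripts were counted in 200 single medullary thymic epithelial cells, the cells that show tissue-restricted self antigens to developing T cells. There were 61 WT GFPhi, 39 WT GFPlo, 48 KO GFPhi and 52 KO GFPlo cells. Group sums were 3468109, 2260672, 3011900 and 1847240 counts, with median totals per cell of 34324, 26266, 42732 and 23115.5. Cells were sorted on 2 dates, with 23 and 38 WT GFPhi, 18 and 21 WT GFPlo, 9 and 39 KO GFPhi, and 22 and 30 KO GFPlo cells on the first and second. No animal is named, so each group was 1 sample, no difference was tested, and differences between animals stay open. Levels are counts per 1000000 of the group sum (CPM) with 95% intervals for counting error of tags, and values by date are given in the order of the dates.

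Aire, which encodes the regulator that lets these cells transcribe genes of other tissues, lies on chromosome 10 (78030022–78043610, minus strand, mm10). Its level was 537 CPM (512–562) in WT GFPhi and 244 (224–265) in WT GFPlo cells, and 815 (783–848) in KO GFPhi and 316 (291–342) in KO GFPlo cells. The higher gate thus held 2.20 times (2.00–2.43) the Aire level in WT and 2.58 times (2.36–2.83) in KO cells. KO cells had 1.52 times (1.43–1.61) the WT level in GFPhi and 1.29 times (1.15–1.46) in GFPlo. Cells with more leukocyte than epithelial counts (leukocyte-marked cells) numbered 22 of 61 in WT GFPhi, 1 of 48 in KO GFPhi, 8 of 39 in WT GFPlo and 16 of 52 in KO GFPlo, and without them the log2 ratio of Aire in GFPhi was 0.18 instead of 0.60. Counts of Aire were found in 93.4% of WT GFPhi cells (84.1–98.2%), 66.7% of WT GFPlo (49.8–80.9%), 89.6% of KO GFPhi (77.3–96.5%) and 67.3% of KO GFPlo cells (52.9–79.7%). The labels do not say which part of Aire is lost, so a transcript counted from its end does not speak to the loss of the protein. By date, the Aire level of WT GFPlo cells was 465 and 38.4 CPM and that of KO GFPlo cells 622 and 138, against 631 and 489 in WT GFPhi and 866 and 795 in KO GFPhi cells. Without pool 5 the log2 ratio of Aire between KO and WT GFPlo cells was −0.03 and without pool 6 it was 1.01, and without pool 6 that between WT GFPhi and GFPlo cells was 1.82.

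The first comparison asked which tissue antigens depend on Aire in the cells that express it most, KO against WT in GFPhi. Most tissue antigens had a lower level in KO GFPhi cells: 89 of 110 with at least 10 counts in the pair, with a median log2 ratio of −4.34, and 37 of them had 0 counts in KO. The median of all 15033 genes with that many counts was −0.13. By date the medians were −4.07 and −4.18 over the 61 and 96 antigens with 10 counts on that date, and −0.40 and −3.02 over the same 110, of which 26 and 7 had 0 counts in both groups. Without leukocyte-marked cells the median over the same 110 was −3.38. Over the 134 antigens with at least 10 counts in the 4 groups the median was −3.21, at percentile 0 of random lists, and without pool 8 it was −2.56. Against this, the list of antigens cited most often as dependent on Aire had a higher summed level in KO, 3095 against 2487 CPM (ratio 1.24, 1.21–1.28, 0.810 and 1.73 by date), which was due to the milk casein Csn2, and without Csn2 the ratio was 0.198.

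**Figure D1:**
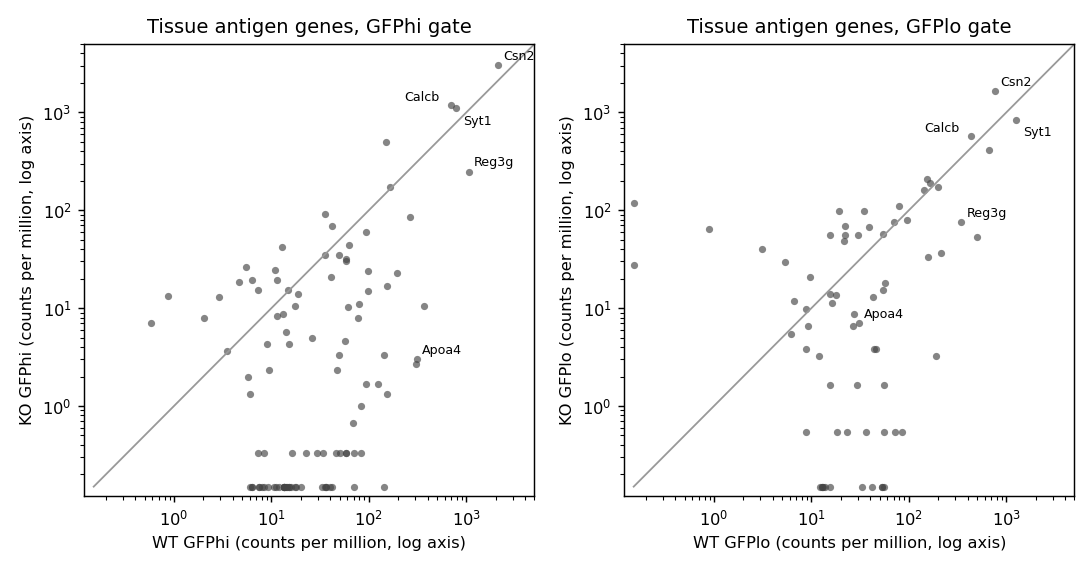
Level of each tissue antigen in counts CPM (log axes) in WT cells (horizontal) against KO cells (vertical), for 103 antigens with at least 20 counts in GFPhi and 69 in GFPlo, with a count of 0 drawn at 0.15 and the line marking equal levels. Below the line lie 83 antigens in GFPhi, 32 of them at 0 in KO, and 45 in GFPlo, 11 of them at 0 in KO.

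Liver plasma proteins had the lowest ratio among the tissue lists, 70.4 against 937 CPM (ratio 0.0751, 0.0650–0.0863, 0.0368 and 0.0816 by date), with 12 of 14 members lower. Apoc3, an apolipoprotein of triglyceride-rich particles, was at 2.66 against 305 CPM, 115-fold lower (58–266). The lectin Mbl2 was at 0 against 66.0, at least 66.3-fold lower. The lipid carrier Apoa4, which led the list, was 104-fold lower (54.6–228), with 78.6% of its WT counts in 1 cell, and without it the ratio was 0.108. Products of the pancreas were at 261 against 1524 CPM (0.171, 0.159–0.185, 0.330 and 0.139 by date), with 13 of 14 members lower. The protease precursor Ctrb1 was at 0 against 144 CPM, at least 145-fold lower, and the islet peptide Iapp at 0 against 70.9, at least 71.2-fold lower. The antibacterial lectin Reg3g (chromosome 6, 78466269–78468872) was 4.29-fold lower (3.96–4.65), with log2 ratios of −0.33 and −2.51 by date, and without it the pancreas ratio was 0.0300. Insulin (Ins2) was at 0 against 1.44 CPM, too few counts to tell levels apart (ratio below 1.26).

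Gut products were at 219 against 514 CPM (0.426, 0.389–0.467, 0.585 and 0.350 by date), with 11 of 16 members lower. Among them was the mucin Muc13, 252-fold lower (44.8–9982), with 61.7% of its WT counts in 1 cell. Its log2 ratio was −7.39, but −4.16 without leukocyte-marked cells and −5.01 with ls primers. Secreted products of salivary, lacrimal and airway glands were at 81.0 against 704 CPM (0.115, 0.10–0.131, 0.143 and 0.106 by date) and were lower in 11 of 11 members. This sum was led by Bpifa1, without which the ratio was 0.211. The salivary protein Bpifa2 was at 0 against 40.4 CPM, at least 40.5-fold lower, and Spt1, a salivary protein, was 6.56-fold lower (4.8–9.17, log2 −6.71 and −2.47 by date). Cornified and stratified epithelium products were at 294 against 1049 CPM (0.281, 0.261–0.302, 0.300 and 0.266 by date), with 18 of 21 lower. Their cornified envelope protein Sprr1b was at 0 against 36.3, at least 36.5-fold lower. Products of testis, epididymis, prostate and seminal vesicle were at 119 against 250 CPM (0.477, 0.421–0.540, 0.349 and 0.861 by date), a sum led by Crisp1, with 5 of 9 lower and a ratio of 1.22 without Crisp1. Without pool 5 the log2 ratio of that list was −0.36.

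Milk proteins and neuronal products had a higher summed level in KO over both dates together. Csn2 (chromosome 5, 87692624–87699630), a casein and the most abundant antigen, was at 3018 against 2097 CPM, 1.44 times (1.40–1.48) the WT level, with log2 ratios of −0.16 and 1.08 by date. The milk list was at 3019 against 2188 (1.38, 1.34–1.42, 0.892 and 1.94 by date), and without Csn2 the ratio was 0.0110, with 3 of 4 members lower. Neuronal and neuroendocrine products were at 2598 against 2283 CPM (1.14, 1.1–1.17, 1.45 and 1.01 by date), with a log2 ratio of −0.092 without leukocyte-marked cells. The neuropeptide gene Calcb, which led that list, was at 1.71 times (1.63–1.80) and the synaptic vesicle protein gene Syt1 at 1.40 times (1.33–1.48) the WT level, while 12 of 16 members were lower and the ratio without Calcb was 0.883. Antigens cited as dependent on Fezf2 or independent of Aire were at 616 against 724 CPM (0.850, 0.800–0.903, 1.38 and 0.385 by date), with 7 of 8 lower, 0.196 without the leading Maoa and a log2 ratio of 0.11 without pool 11.

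Gene families that serve secretion and barriers followed the same direction. Kallikreins, secreted proteases, were at 64.7 against 647 CPM (0.10, 0.0860–0.116, 0.0778 and 0.104 by date), with 18 of 20 members lower, a log2 ratio of −0.17 with umi primers and Klk1 at 0 against 131, at least 131-fold lower. Lipocalins and odorant binding proteins were at 0.664 against 208 (0.00319, 0.000386–0.0116), with 6 of 6 lower, among them the iron-binding Lcn2, at 0 against 84.8 and at least 85.1-fold lower. Obp2a of that family was 140-fold lower (24.7–5557), with 54% of its WT counts in 1 cell. Major urinary proteins, pheromone carriers made by the liver, were at 0.332 against 31.7 (0.0105, 0.000263–0.0595), with 1 count in KO and all 110 WT counts on the first date, so the second date holds no comparison. BPI fold proteins were at 29.2 against 470 (0.0621, 0.0496–0.0770, 0.436 and 0.0371 by date), again led by Bpifa1 (0.186 without it), with a log2 ratio of 1.81 with umi primers. Secretoglobins were at 23.6 against 266 (0.0886, 0.0686–0.113, 0.0335 and 0.193 by date) through Scgb1c1, the only member with 10 counts, and at 1.15 without it. Without pool 6 the log2 ratio of this family was −2.13. Small proline-rich and late cornified envelope proteins were at 22.9 against 315 (0.0727, 0.0561–0.0928, 0.418 and 0.00484 by date), with 13 of 13 lower and a log2 ratio of −7.13 without pool 4. Their leading gene Sprr1a was 8.4-fold lower (6.54–10.9), with 91.3% of its KO counts in 1 cell and a log2 ratio of −6.42 without pool 4.

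Mucins were at 83.3 against 200 CPM (0.416, 0.359–0.482, 0.413 and 0.422 by date), a ratio of 0.0646 without Muc1. Defensins had a ratio of 0.449 (0.395–0.509, 0.725 and 0.308 by date), the carcinoembryonic antigen family of 0.370 (0.320–0.426, 0.237 and 0.539), and UDP-glucuronosyl and glutathione transferases of 0.405 (0.369–0.444, 0.243 and 0.491, log2 −0.25 with umi primers). Cytochrome P450 enzymes were at 0.484 of the WT level (0.451–0.520, 0.711 and 0.382), claudins at 0.569 (0.528–0.612, 0.391 and 0.703, log2 0.20 with umi primers) and serpins at 0.853 (0.823–0.884, 0.748 and 0.947, and 1.09 without Serpinb1a). Chemokines had a ratio of 0.682 (0.666–0.698, 0.864 and 0.600), with 17 of 24 lower, and 0.461 without Cxcl10. S100 proteins were at 3586 against 4903 CPM (0.731, 0.714–0.749, 0.466 and 0.923), with the calcium-binding S100a8 23.5-fold lower (20.1–27.7, log2 −2.06 with umi primers), at 53.1 against 1248. Keratins as a sum were at 4724 against 3661 (1.29, 1.26–1.32, 1.13 and 1.41), although 17 of 27 keratins were lower.

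**Figure D2:**
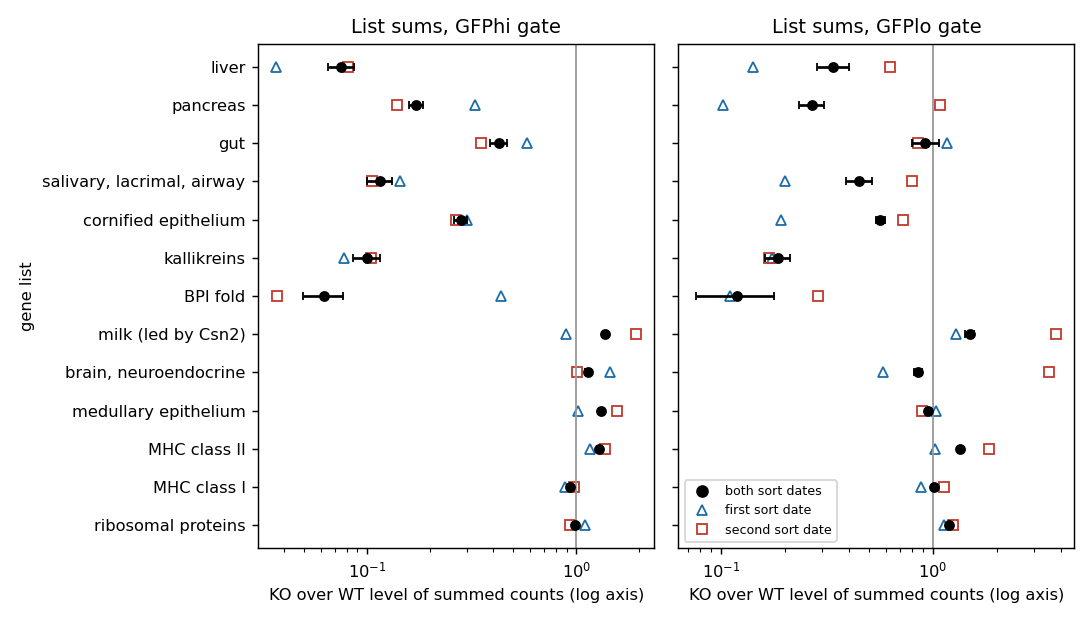
Ratio of the summed level in KO over WT cells (log axis) for 13 gene lists, in GFPhi (left) and GFPlo (right). Black points with 95% counting intervals stand for both dates together, blue triangles for the first date and red squares for the second. In GFPhi, liver products were at 0.0751, kallikreins at 0.10 and MHC class II presentation at 1.28.

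Among the 12 ranked lower genes, Retnla, a secreted resistin-like protein (chromosome 16, 48842551–48844461), was at 0.996 against 461 CPM, 463-fold lower (158–2247), with counts in 2 of 48 KO and 15 of 61 WT cells. Saa1, an acute-phase plasma protein, was 380-fold lower (67.8–15024), and the alarm cytokine Il33 was at 0 against 128, at least 129-fold lower, with 1 count in the pair on the first date and a log2 ratio of −9.70 on the second. Fbln1, a matrix glycoprotein, was at 9.30 against 830, 89.3-fold lower (61.7–135), with counts in 17 KO and 30 WT cells and a log2 ratio of −0.83 with umi primers. The antibody-joining chain Igj, at 89.3 against 5301, was 59.3-fold lower (52.6–67.2), and Mzb1, a protein of antibody-secreting cells, was 152-fold lower (59.1–559), with 0 counts in both groups on the first date and a log2 ratio of −7.19 on the second. Of their WT counts, 17023 of 18383 and 634 of 700 lay in 6 cells rich in immunoglobulin transcripts, all of the second date, while Igj also had 931 against 2 counts on the first date, 647 of them in 1 cell. Without leukocyte-marked cells the log2 ratios were −1.06 for Igj and −2.53 for Mzb1. Of the 10 ranked lower genes with at least 10 counts in the pair on each date, all 10 were lower on both. Since the ranking used both dates together, this was largely set in advance and is no separate check.

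Higher in KO GFPhi cells were genes of varied function. The intermediate filament gene Synm (chromosome 7, 67730160–67759742) was at 79.0 against 0.577 CPM, 137 times the WT level (37.5–1138), with counts in 13 KO and 2 WT cells. The neurotrophin gene Ntf5 was at 210 against 3.17, 66.1 times (36.7–133), and the cell cycle gene Cdca7l at 122 against 2.88, 42.3 times (22.7–88.9). Catsper3, a sperm channel subunit, was at 38.5 against 0 (at least 44.5-fold), Asphd1 at 35.2 against 0 (at least 40.7-fold), Six5 at 23.6 against 0 (at least 27.3-fold) and AC163677.1 at 23.9 against 0 (at least 27.6-fold). With 1 count each in WT, Id1 was 157 times (27.6–6230), Gtpbp6 147 times (26–5866), Galk1 138 times (24.3–5503) and Epb4.9 124 times (21.9–4957) the WT level. The acetylcholine receptor gene Chrna3 was 36 times the WT level (24.9–54.1), in 10 KO and 19 WT cells, with log2 ratios of −1.33 and 6.05 by date. Of the 11 with at least 10 counts in the pair on each date, 10 were higher on both, again no separate check of direction.

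MHC class II presentation in GFPhi was at 30833 against 24014 CPM in KO against WT (1.28, 1.27–1.30, 1.17 and 1.37 by date), with 12 of 14 members higher, and its H2-Aa and H2-Ab1 chains were at 1.49 (1.46–1.52) and 1.33 times (1.30–1.36) the WT level. Medullary markers were at 9496 against 7202 (1.32, 1.30–1.34, 1.03 and 1.57), with 17 of 23 members higher, the costimulatory ligand Cd80 4.66 times (2.83–8.03), the adhesion molecule Epcam 1.21 times (1.1–1.33) and Krt8 1.51 times (1.45–1.58) the WT level. The log2 ratio of Epcam was −0.12 without leukocyte-marked cells and −0.88 with umi primers. Leukocyte-marked cells held a large part of the WT GFPhi counts. The log2 ratio of the WT to the KO group sum in GFPhi was 0.20 with them and −0.70 without. Their counts lower the WT level of epithelial genes, so ratios of medullary markers above 1 may in part reflect this. The basal keratin Krt5 (4.88, 4.06–5.91) had 1 count in the pair on the first date and a log2 ratio of 2.18 on the second, and Krt14 (1.792, 1.63–1.98) had −1.21 and 1.1 by date. Fezf2, a second regulator of tissue antigens (chromosome 14, 12342094–12348189), was at 532 against 859 CPM (0.620, 0.583–0.659, log2 −0.98 and −0.24 by date), with a log2 ratio of 1.65 with umi primers. MHC class I presentation was at 0.936 of the WT level (0.924–0.949, 0.886 and 0.972), with B2m at 0.963 (0.945–0.982), whose log2 ratio lay above 0 without pool 6 (0.07) or pool 11 (0.04). Partners of Aire were at 1.02 (0.996–1.05, 0.904 and 1.08), with 12 of 24 lower, the deacetylase Sirt1 at 2.05 (1.92–2.19, log2 −0.62 with umi primers) and the histone chaperone Supt16 at 0.363 (0.327–0.402, log2 −0.18 with ls and −3.79 with umi primers).

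Markers of other cells were lower, level or led by few genes. Dendritic, macrophage and B cell markers were at 283 against 635 CPM (0.445, 0.411–0.482, 0.490 and 0.426 by date), with the leukocyte phosphatase Ptprc 14.8-fold lower (8.50–28.3, log2 −0.21 without leukocyte-marked cells) and the B cell receptor chain Cd79a 4.63-fold lower (3.51–6.19, log2 −0.98 without leukocyte-marked cells). Thymocyte markers were at 0.858 (0.786–0.936, 0.664 and 0.998), with a log2 ratio of 0.04 without pool 5, and fibroblast and endothelial markers at 0.747 (0.705–0.792, 0.938 and 0.664). Cortical epithelial markers were at 1.30 (1.25–1.35, 1.19 and 1.59), a sum led by Tbata at 2.26 times (2.15–2.38) the WT level and at 0.614 without it, with a log2 ratio of −0.20 without leukocyte-marked cells. Tuft cell markers were level at 80.7 and 80.2 CPM (1.01, 0.844–1.20, 0.517 and 1.18). Proliferation genes were at 0.729 (0.700–0.760, 0.286 and 0.773), with log2 ratios of 0.017 without leukocyte-marked cells and 1.70 with umi primers, immediate early and heat shock genes at 1.04 (1.02–1.05, 1.0 and 1.03, and 0.846 without Hspa8) and ribosomal protein genes at 0.983 (0.979–0.988, 1.1 and 0.930). Red cell genes were at 43.2 against 19.6 CPM (2.20, 1.63–3.0), from Alas2 alone among members with 10 counts.

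The second comparison asked the same in cells with low GFP, KO against WT in GFPlo. Tissue antigens were again lower, but by their median on the first sort date only: 74 of 105 with at least 10 counts in the pair were lower, with a median log2 ratio of −2.07, and by date the medians were −4.18 and 0.20 over the 85 and 65 antigens with 10 counts on that date. With groups at 0 set to 3 counts these medians were −1.88, and −2.05 and 0.21 by date. Over the same 105 antigens the first-date median was −3.22, and the second-date median equalled the value of the 21 antigens with 0 counts in both groups, so it says nothing on direction. Over the 134 antigens the median was −1.29, at percentile 0, and −0.66 without pool 1. Kallikreins were lower on both dates, at 131 against 708 CPM (0.185, 0.161–0.212, 0.175 and 0.169), with 16 of 18 lower. Of the WT GFPlo cells, those of the first date had an Aire level of 465 CPM and those of the second 38.4, so that the WT side of this comparison was not the same on the 2 dates.

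Liver products in GFPlo were at 90.9 against 270 CPM (0.337, 0.282–0.400, 0.141 and 0.626 by date), with 11 of 13 lower. Pancreas products were at 141 against 527 (0.268, 0.233–0.307, 0.102 and 1.08), with 10 of 11 lower and Reg3b at 0 against 52.6, at least 32.4-fold lower, and without pool 1 the log2 ratio of this list was −1.21. Gland secretions were at 148 against 332 (0.447, 0.387–0.513, 0.200 and 0.798), with Spt1 at 0 against 42, at least 25.9-fold lower, and their log2 ratio was −1.91 without pool 11 and 0.023 with umi primers. Cornified products were at 1399 against 2477 (0.565, 0.539–0.592, 0.192 and 0.719), with log2 ratios of −1.76 without pool 12 and 0.20 with ls primers. BPI fold proteins were at 0.119 (0.0764–0.179, 0.111 and 0.287). Gut products, at 0.921 (0.797–1.06, 1.16 and 0.848), and neuronal products, at 0.851 (0.815–0.887, 0.578 and 3.52), did not keep 1 direction. The cited Aire-dependent antigens were at 1673 against 935 CPM (1.789, 1.69–1.89, 1.63 and 3.50), again through Csn2 at 2.15 times (2.02–2.28) the WT level, with a ratio of 0.130 without it. Milk proteins as a list were at 1.49 (1.41–1.57, 1.29 and 3.82), at 0.0400 without Csn2 and at −0.18 in log2 as the mean of cells.

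Among single genes lower in KO GFPlo cells, the liver enzyme gene Bhmt (chromosome 13, 93616675–93637961) was at 3.25 against 331 CPM, 102-fold lower (46.6–278), in 6 of 52 KO and 7 of 39 WT cells. The milk protein gene Csn1s2a was 212-fold (37.7–8391) and the protease gene Klk6 195-fold lower (34.7–7745). Fkbp11, of secretory cells, was 233-fold lower (41.5–9230) with 159 of its 285 WT counts in 2 second-date cells rich in immunoglobulin transcripts and 119 in 1 cell of the first date. At 0 in KO were Ppp3cc (at least 40.6-fold), Clec2l (at least 38.1-fold), Mtbp (at least 34.6-fold) and Calb1 (at least 34-fold, log2 −7.29 on the first date, with 0 counts in both groups on the second). Higher in KO were the T cell surface gene Thy1, at 136 against 1.33 CPM and 103 times the WT level (34.8–502), and the blood cell adhesion gene Fermt3, 119 times (32.6–992, log2 6.58, and 2.93 without leukocyte-marked cells). Fbxl18 (at least 44.5-fold), Nipsnap1 (at least 40.4-fold) and the cytokine receptor gene Il7r (at least 30.6-fold) were at 0 in WT, and Gal3st2 (173 times, 30.5–6863), Hsdl1 (144 times, 25.4–5752) and Tm4sf20 (137 times, 24.1–5462) had 1 WT count. Without leukocyte-marked cells log2 ratios fell from 7.53 to 5.65 for Il7r, from 7.93 to 6.71 for Nipsnap1 and from 6.60 to 5.53 for Hsdl1. That of Gal3st2 rose from 6.85 to 8.54. With at least 10 counts in the pair on each date, 6 of 6 higher and 6 of 6 lower genes had the same direction on both. The ranking over both dates largely fixed this.

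Dendritic, macrophage and B cell markers in GFPlo were at 1963 against 848 CPM (2.31, 2.19–2.45, 1.35 and 2.31 by date), with 10 of 13 members higher, and the log2 ratio was 1.91 without pool 11, 0.60 without pool 12, −0.14 without leukocyte-marked cells and −0.16 with umi primers. The lysozyme gene Lyz2 was at 2.21 times the WT level (1.99–2.46), with log2 ratios of −3.41 and 2.88 by date of −0.41 without pool 12 and of −2.58 without leukocyte-marked cells, and 63.4% of its KO counts lay in 1 cell. Cd79a was at 2.03 times (1.84–2.24), with 84.8% of its WT counts in 1 cell and log2 ratios of 3.68 without pool 11, 0.52 without pool 12 and −0.34 with umi primers. Thymocyte markers were at 454 against 227 CPM (2.00, 1.786–2.23, 1.53 and 2.10) as a sum, with 6 of 11 members lower. MHC class II presentation was at 1.34 (1.32–1.36, 1.02 and 1.84), with the lysosomal reductase Ifi30 at 3.13 times (2.84–3.45) and H2-Aa at 1.42 times (1.38–1.46, log2 −0.10 and 1.12 by date) the WT level. Medullary markers were at 0.943 (0.922–0.965, 1.03 and 0.892) and at 0.085 in log2 without leukocyte-marked cells, with 13 of 23 members higher, Epcam at 0.498 (0.449–0.551), Krt8 at 0.666 (0.628–0.706), Krt14 at 0.365 (0.316–0.421, log2 −0.38 with ls primers) and the tight junction gene Cldn3 4.13-fold lower (3.11–5.55). Fezf2 was at 1.28 (1.16–1.41), and at −0.09 in log2 without pool 5. Keratins were at 0.653 (0.634–0.673, 0.784 and 0.572). Proliferation genes were at 0.549 (0.524–0.575), but at 14 and 0.206 by date, and in log2 at 0.04 without pool 11 and 1.13 without leukocyte-marked cells.

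The third comparison asked how antigens follow GFP in WT cells, GFPhi against GFPlo. Tissue antigens were somewhat higher in WT GFPhi cells, in 72 of 129 with at least 10 counts in the pair, with a median log2 ratio of 0.56, but the medians by date were −1.08 and 3.65, over the 101 antigens with 10 counts on each date, and −0.60 and 2.49 over the same 129. Without leukocyte-marked cells the median over these 129 was 0.076. Over the 134 antigens the median was 0.60, at percentile 99.9, and it was −0.10 without pool 11. The cited Aire-dependent antigens were higher as a sum on both dates, with 6 of 12 members higher, at 2487 against 935 CPM (2.66, 2.54–2.79, 2.44 and 5.46), and at 2.34 without Csn2. Fezf2 was also higher on both, 859 against 355 CPM (2.42, 2.24–2.62, log2 1.25 and 2.59 by date).

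By tissue, liver products were at 937 against 270 CPM (3.47, 3.19–3.79, 1.75 and 6.0 by date), with 10 of 16 higher. Apoc3 was 57.4 times (32.7–111) and the apolipoprotein Apoa4 10.2 times (7.99–13.2) the GFPlo level, the latter with 78.6% of its GFPhi counts in 1 cell and log2 0.86 without pool 11, and without pool 11 the log2 ratio of the list was 1.07. Gut products were at 514 against 197 (2.61, 2.35–2.90, 2.10 and 4.76), with 13 of 19 higher. Pancreas products were at 1524 against 527 (2.89, 2.71–3.08), with 0.809 and 12.3 by date and a log2 ratio of 2.24 without pool 1, 0.83 without pool 11 and −0.099 as the mean of cells. Reg3g followed them, at 3.08 times (2.85–3.33) with log2 −1.08 and 3.93 by date and −0.13 as the mean of cells. Gland secretions were at 2.12 (1.95–2.30, 0.646 and 3.99), at 1.06 without Bpifa1, and at 0.39 in log2 without pool 12. Cornified products went the other way, at 1049 against 2477 (0.423, 0.406–0.442, 0.277 and 0.465), with 14 of 22 lower and the skin protein gene Krtdap 11-fold lower (9.50–12.7, log2 0.14 with ls primers), and the log2 ratio of the list was −1.85 without pool 11. The filament gene Flg was at 0 against 48.7, at least 56.3-fold lower. The basal keratin Krt5 was at 40.7 against 529, 13-fold lower (10.9–15.6, log2 −5.12 and −4.01 by date), and Epcam 2.29-fold lower (2.10–2.5).

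Higher genes in WT GFPhi were Retnla, at 461 against 4.42 CPM and 104 times the GFPlo level (56.5–218), the muscle methyltransferase gene Smyd1 (104 times, 35.5–508), Timd2 (129 times, 35.6–1072) and Il33 (145 times, 39.9–1201, with 1 count per group on the first date and log2 7.24 on the second). Without pool 12 the log2 ratio of Il33 was 5.10. At 0 in GFPlo were the gut esterase gene Ces2e (at least 61.9-fold), Iapp (at least 53.5-fold), the DNA repair gene Ung (at least 47.6-fold) and Arl4a (at least 60.6-fold), the last in 29 of 61 against 0 of 39 cells. Lower were Bhmt, at 1.15 against 331 and 287-fold lower (112–1056), and the transcription factor gene Insm2, 77.4-fold lower (45.8–142) but with a log2 ratio of 0.12 with ls primers. The log2 ratio of Bhmt was −10.64 without pool 11 and −6.99 without pool 2. Csn1s2a was 397-fold (70.7–15754) and Copz2 299-fold lower (53.1–11876), each with 1 count in GFPhi. Clec2l (at least 71.6-fold), the serine protease gene Htra1 (at least 65.5-fold) and B3galt2 (at least 63.4-fold) were at 0 in GFPhi. The 7 higher genes with at least 10 counts in the pair on each date were higher on both. The lower genes given here were lower on both, except B3galt2, which had 0 counts in both groups on the second. Ranked on both dates together, these genes give no separate check of direction.

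Of functions and other cells in WT, MHC class II presentation was at 1.18 times the GFPlo level (1.17–1.20, 1.08 and 1.46 by date), while its protease gene Ctsl was 7.20-fold lower (6.28–8.27). The chemokine gene Ccl19 was at 1266 against 503 CPM (2.52, 2.36–2.69, log2 2.35 and 0.59 by date) and S100a14 at 753 against 269 (2.80, 2.56–3.06). Cortical epithelial markers were at 1535 against 2773 (0.553, 0.533–0.574, 0.601 and 0.783), with a log2 ratio of −0.16 without pool 4. Tuft cell markers were at 80.2 against 205 (0.391, 0.336–0.455), but 2.10 and 0.226 by date and 0.60 in log2 without pool 11. Proliferation genes were at 0.665 (0.641–0.689), with 5.96 and 0.439 by date and a log2 ratio of 1.57 without leukocyte-marked cells.

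The fourth comparison asked which differences between the gates remain without Aire, GFPhi against GFPlo in KO. Tissue antigens were lower in the higher gate over both dates together and on the second, but not on the first. Of 71 with at least 10 counts in the pair, 42 were lower, with a median log2 ratio of −1.21. By date the medians were 0.28 and −1.02 over the 36 and 64 antigens with 10 counts on that date. On the first date 16 were lower and 20 higher. Medians over fixed sets of antigens by date equalled the value of antigens with 0 counts in both groups and are not read here. Among the lowest were cornified products, at 294 against 1399 CPM (0.211, 0.195–0.227, 0.434 and 0.172), with 14 of 16 lower and log2 ratios of −1.54 without pool 12 and 1.63 with umi primers. Csn2 was higher, at 1.83 times (1.75–1.90), and with it the cited Aire-dependent antigens, at 3095 against 1673 CPM (1.85, 1.78–1.93, 1.21 and 2.70), a ratio of 3.56 without Csn2.

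Among the ranked genes lower in KO GFPhi, Calm4, a calmodulin of the epidermis (chromosome 13, 3837757–3838673), was at 0 against 133 CPM, at least 134-fold lower, and Sprr1b at 0 against 56.8, at least 57.1-fold lower. The envelope protein gene Rptn (396-fold, 70.4–15713), Amigo2 (368-fold, 65.5–14618) and the B cell gene Ms4a4c (263-fold, 46.5–10432) had 1 count in GFPhi. Small proline-rich and late cornified envelope proteins were at 22.9 against 278 (0.0825, 0.0632–0.106, 0.556 and 0.00516 by date), and −6.79 and −2.67 in log2 without pools 4 and 12 and 6.26 with umi primers. Krtdap was 40.2-fold lower (28.1–59.6), with 0 counts in both groups on the first date and a log2 ratio of −5.49 on the second. Its log2 ratio over both dates was −5.31, but −3.94 without pool 12 and −3.68 as the mean of cells. St3gal1 (at least 69.0-fold) and Siglecg (at least 58.2-fold) were at 0 in GFPhi, and Fermt3 was 159-fold lower (43.4–1322, log2 −6.99, and −3.74 without leukocyte-marked cells). Higher in KO GFPhi were the stress cytokine gene Gdf15, at 219 against 4.33 CPM and 50.7 times the GFPlo level (25.6–118) in 29 of 48 against 4 of 52 cells, and the replication gene Mcm7, 55.8 times (26.9–139). Ntf5 (38.7 times, 20.9–81.1), Ppp2r5d (111 times, 30.6–923) and the transporter gene Slc22a7 (258 times, 46–10198) were also higher, Klrg1 and Cdk16 were at 0 in GFPlo (at least 24.1-fold each), and Chrna3 was 37.1 times (22.4–66.5, log2 −1.68 and 6.76 by date). With at least 10 counts in the pair on each date, 6 of 7 higher and 8 of 8 lower genes had the same direction on both. Here too the ranking over both dates largely fixed this.

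Dendritic, macrophage and B cell markers were lower in KO GFPhi cells, at 283 against 1963 CPM (0.144, 0.133–0.155, 0.427 and 0.104 by date), with 11 of 12 lower and a log2 ratio of −0.47 without leukocyte-marked cells. Cd79a was 27.9-fold (21.5–36.7, log2 −2.49 without leukocyte-marked cells) and Lyz2 9.83-fold lower (8.33–11.7), and the log2 ratio of Lyz2 was −1.90 without pool 12, 0.63 without leukocyte-marked cells and 2.18 with umi primers. Medullary markers were at 9496 against 7318 (1.30, 1.27–1.32, 1.26 and 1.33, log2 −0.052 without leukocyte-marked cells), with Krt8 at 1.86 times (1.76–1.96) and the surface gene Ly6d 5.55-fold lower (4.68–6.61). MHC class II presentation was at 1.13 (1.12–1.14, 1.23 and 1.09), with 7 of 14 members higher and H2-Aa at 1.27 (1.24–1.30). Reg3g was at 247 against 75.8 CPM, 3.26 times (2.72–3.93, log2 1.57 and 1.75 by date).

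The number of tissue antigens per cell at 13300 counts had medians over both dates of 15.5 in WT GFPhi, 12 in WT GFPlo, 10 in KO GFPhi and 9 in KO GFPlo. By date these were 14 and 18, 17 and 9, 11 and 10, and 10 and 7.5. Over a whole group, without thinning, 136, 123, 82 and 102 of 190 antigens had a count. These numbers are not matched for the cells and total counts of the groups, which differed. The antigen level without Csn2 was 7653 and 6802 CPM in WT GFPhi and GFPlo and 4180 and 4239 in KO GFPhi and GFPlo cells. By date it was 6421 and 8278 in WT GFPhi, 9717 and 4097 in WT GFPlo, 6130 and 3410 in KO GFPhi, and 3939 and 4413 in KO GFPlo cells.

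**Figure D3:**
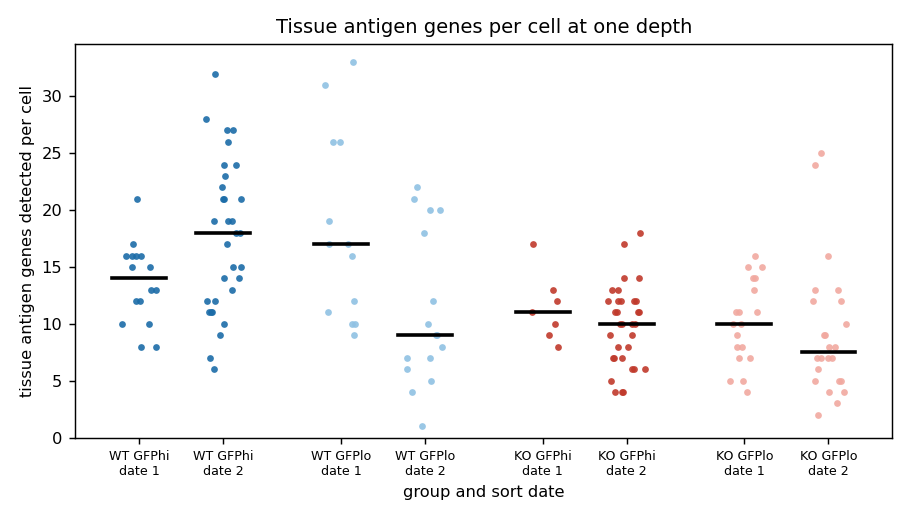
Number of tissue antigens with a count in each cell at 13300 counts (vertical axis), by group and sort date, with bars at medians. Medians were 14 and 18 in WT GFPhi, 17 and 9 in WT GFPlo, 11 and 10 in KO GFPhi, and 10 and 7.5 in KO GFPlo cells on the first and second date.

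The number of genes detected per cell was similar with and without Aire in GFPhi. At 13300 counts, median genes per cell were 3089 (quartiles 2904–3388) in WT GFPhi, 3099 (2681–3316) in WT GFPlo, 3100 (2701–3454) in KO GFPhi and 2731 (2460.0–3359) in KO GFPlo cells. The KO over WT ratio of medians was 1.0 in GFPhi (1.07 and 0.944 by date) and 0.881 in GFPlo (0.870 and 0.899). Rare genes, found in 1 to 10% of cells, had medians of 374, 391, 324 and 326, a KO over WT ratio of 0.866 in GFPhi (0.925 and 0.864) and 0.834 in GFPlo (0.896 and 0.837). Between gates the GFPhi over GFPlo ratio of genes per cell was 0.997 in WT (0.959 and 1.03) and 1.14 in KO (1.17 and 1.09), and that of rare genes was 0.957 (0.954 and 0.975) and 0.994 (0.984 and 1.01).

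Summed with Csn2, the cited Aire-dependent antigens were higher in KO in both gates. That rise was smaller in GFPhi than in GFPlo, by a log2 difference of −0.52 (−0.61 to −0.43, −1.01 and −1.02 by date). This difference was 0.13 as the mean of cells and −0.94 to −0.00071 with each pool left out. It rested on Csn2, since without Csn2 the difference was 0.60 (0.09–1.12), with −0.66 and 1.786 by date. For other lists, a negative difference stands for a lower KO to WT ratio in GFPhi. By list it was −2.17 for liver (−1.94 and −2.94 by date) and −1.11 for gut (−0.99 and −1.27). Glands had −1.96 (−0.48 and −2.92) and milk −0.11 (−0.53 and −0.98). Pancreas (−0.65), cornified (−1.01), male reproductive (−0.64), neuronal (0.42) and Fezf2-dependent or Aire-independent antigens (−0.10) changed sign between dates. Across genes, the log2 ratios of the 2 sort dates had Pearson correlations of 0.190 for KO against WT in GFPhi, 0.103 in GFPlo, 0.0720 for GFPhi against GFPlo in WT and 0.224 in KO, so single genes repeated weakly between dates.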

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

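All tests of the immunoglobulin pattern below, the Aire and depth tests of the GFPlo pattern, and the all-gene test of the GFPhi pattern were chosen after the result was seen, and the others before.

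In cells sorted as CD45-negative, a gate that takes out most blood cells, immunoglobulin transcripts reached at least 1% of counts in 8 cells, all WT and all of the second date, with the largest shares 18% and 15%, and the immunoglobulin level was 18493 per 1000000 counts in WT GFPhi and 396 in KO GFPhi cells. If these were B-lineage cells alone in their wells, most should lack epithelial transcripts, but 2 of 8 lay under 25% of the median epithelial level. If epithelial cells shared their wells with B-lineage RNA, most should keep that level, and 4 of 8 kept at least 50% of it, which left this undecided. The 8 cells may thus be of both kinds. Of the WT GFPhi counts of Igj and Mzb1 they held 17023 of 18383 and 634 of 700, and of the WT GFPlo counts of Fkbp11 159 of 285. On the first date, which had none of these cells, Igj had 931 counts in WT GFPhi against 2 in KO GFPhi and Fkbp11 125 in WT GFPlo against 1 in KO GFPlo cells, but 647 of these 931 and 119 of these 125 counts lay in 1 further cell each.

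The genotype difference of tissue antigens in GFPlo was found by median on the first date only, with values of −4.18 and 0.20 over members with 10 counts on each date. Too few counts of the WT GFPlo cells on the second date would hide their antigens, but their total was 1172521 against 1088151 counts on the first, a ratio of 1.08, which argued against this. Leukocyte-marked cells were tested by leaving them out, and the second-date median of 0.29 over 59 antigens argued against them. Less Aire in the WT GFPlo cells of the second date stays open as an explanation, with an Aire level 0.0825 (0.0594–0.112) of that of the first date. Aire was also lower on the second date in KO GFPlo cells (622 and 138 CPM). The median GFP signal at the cytometer was 5960 and 2290 in WT GFPlo and 8337 and 2515 in KO GFPlo cells by date, against 22563 and 20952.5 in WT GFPhi and 22708 and 28917 in KO GFPhi cells. The low gate may thus have held other cells on the 2 dates. The GFP reporter transcript, in the units given below, also fell in WT GFPlo cells, from 529 to 28. In KO GFPlo cells it rose from 300 to 709, so the measures disagree there. Median Ly51 signal by date was −2 and 1392 in WT GFPhi, −7 and 2318 in WT GFPlo, −12 and 1672 in KO GFPhi, and −11.5 and 1420 in KO GFPlo cells. Cytometer signals may thus not be comparable between dates, which was not tested, and neither were different animals.

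The lower tissue antigens in KO GFPhi cells could come from depth or scaling. The median of all genes was −0.13, but levels were already divided by group sums, so a large shift could hardly appear there. That median also does not show how depth acts on rarely detected genes, so it cannot decide. The antigen median lay at percentile 0 of random lists matched on mean level, a description and no test. The lower antigens could also come from single cells that hold most of a gene's counts. Without the top cell of each gene in each group the antigen median was −3.08, with 90 of 110 lower. However, over the 134 antigens a median of 2.08% of KO GFPhi and 9.84% of WT GFPhi cells had counts. Leaving out the top cell can thus empty the KO side while WT keeps counts, so this cannot decide. A difference between the animals of each genotype was not tested.

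The GFP reporter transcript was counted in the metadata but entered none of the comparisons. It was at 1578 per 1000000 unique reads in WT GFPhi, 262 in WT GFPlo, 2638 in KO GFPhi and 545 in KO GFPlo cells. By date it was at 899 and 1909 in WT GFPhi, 529 and 28 in WT GFPlo, 859 and 3262 in KO GFPhi, and 300.2 and 709 in KO GFPlo cells.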

How the results depend on the processing

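Values here are log2 ratios with 0.5 count added, and for genes per cell ratios of medians. The alternatives fixed in advance were all run. Leaving out leukocyte-marked cells, leaving out Csn2, and limiting medians to members with at least 10 counts in the pair were chosen after seeing the data. For lists and genes outside the fixed results, a direction was judged only where both sort dates shared it and only for those the report prints, a rule adopted after a first run, which counts a date without counts by the value the added 0.5 count gives. Over all 691 gene results, 617 had an interval off 0, of which 185 changed sign under some alternative and 110 on a sort date (367 of 12908 values). Over 147 list results these were 133, 67 and 35 (154 of 2915 values). No paired analysis was possible because replicate numbers only name cells. Pools, of which 11 of 12 held cells of all 4 groups, served as blocks of the Mantel-Haenszel ratio.

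For Aire, KO against WT in GFPhi (0.60) was 0.46 and 0.70 on the first and second date, 0.12 with umi primers and 0.18 without leukocyte-marked cells. In GFPlo (0.37) it was 1.83 on the second date and 2.42 with umi primers, and −0.027 to 1.01 with each pool left out. Between gates it was 0.44 and 3.66 by date and 3.13 with umi primers in WT (1.14), and 0.48 and 2.52 by date in KO (1.37).

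For the cited list, KO against WT in GFPhi (0.32) was −0.30 and 0.79 by date and −2.33 without Csn2. In GFPlo (0.84) it was 0.70 and 1.80 by date, 2.36 with umi primers, −0.010 as the mean of cells and −2.93 without Csn2. Between gates in WT (1.41) it was 1.29 and 2.45 by date, 3.59 with umi primers and 0.56 as the mean of cells. In KO (0.89) it was 0.28 and 1.43 by date and 1.82 without Csn2. The sign of the genotype difference thus hung on Csn2.

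For the median of tissue antigens, KO against WT in GFPhi (−3.21) was −0.12 and −2.47 by date, 0.12 with umi primers and −2.07 with groups at 0 set to 3 counts. In GFPlo (−1.29) it was −1.64 and 0.0041 by date and 0.38 with umi primers, and over members with 10 counts in the pair −4.18 and 0.20 by date and −3.33 with umi primers. Between gates in WT (0.60) it was −0.47 and 2.25 by date, −0.48 with umi primers, −0.13 as the mean of cells, −0.10 to 0.93 with each pool left out, and over members in the pair −1.08 and 3.65 by date. In KO (−0.71) it was −0.33 and −0.89 by date and −1.42 without leukocyte-marked cells. These KO values, those with umi primers in the other comparisons (0.12, 0.38 and −0.48) and 0.0041 in GFPlo equalled the value of a member with 0 counts in both groups, which the added 0.5 count and the totals set, so they say nothing on antigens. Over members in the pair in KO it was −1.21, 0.28 on the first date, 0.51 with umi primers and −1.30 without leukocyte-marked cells.

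The difference between gates (−0.52) was −1.01 and −1.02 by date, −0.77 without the cells of lowest depth, −0.33 with ls and −2.15 with umi primers, −0.83 without leukocyte-marked cells, 0.13 as the mean of cells, −0.83 as the Mantel-Haenszel ratio over pools, −0.18 without top cells, 0.59 without Csn2, and −0.94 to −0.00071 with each pool left out.

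For genes per cell, KO over WT in GFPhi (1.0) was 1.09 unthinned and 1.07 and 0.944 by date. In GFPlo (0.881) it was 0.919 at 6650 counts, 0.852 at 23200, 0.919 unthinned, 0.870 and 0.899 by date, 0.919 with ls and 0.823 with umi primers, and 0.860 to 0.926 with each pool left out. Between gates in WT (0.997) it was 1.09 unthinned and 0.959 and 1.03 by date, and in KO (1.14) 1.29 unthinned and 1.17 and 1.09 by date.

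For rare genes, KO over WT in GFPhi (0.866) was 0.984 unthinned, 0.925 and 0.864 by date, 0.790 with umi primers and 0.824 to 0.918 with each pool left out. In GFPlo (0.834) it was 0.899 at 6650 counts, 0.879 at 23200, 0.627 unthinned, 0.896 and 0.837 by date, 0.938 with ls and 0.653 with umi primers, 0.883 without leukocyte-marked cells and 0.815 to 0.923 with each pool left out. Between gates in WT (0.957) it was 0.980 at 6650 counts, 0.975 at 23200, 0.984 unthinned, 0.938 and 1.02 for genes in 1 to 5% and 1 to 20% of cells, 0.954 and 0.975 by date, 1.01 with ls and 0.883 with umi primers, and 0.906 to 1.01 with each pool left out. In KO (0.994) it was 0.953 at 23200 counts, 1.55 unthinned, 0.956 and 1.06 for 1 to 5% and 1 to 20%, 0.984 and 1.01 by date, 0.958 with ls and 1.07 with umi primers, 0.940 without leukocyte-marked cells and 0.929 to 1.05 with each pool left out.

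Among other lists the direction turned with umi primers for gland secretions in GFPlo (0.023), cornified products (1.63) and small proline-rich proteins (6.26) between gates in KO, leukocyte markers in GFPlo (−0.16), and proliferation genes (1.70), BPI fold proteins (1.81) and claudins (0.20) in GFPhi. With ls primers it turned for cornified products in GFPlo (0.20). Without leukocyte-marked cells it turned in GFPhi for neuronal products (−0.092), cortical markers (−0.20) and proliferation genes (0.017), in GFPlo for leukocyte markers (−0.14), and between gates in KO for medullary markers (−0.052). Milk proteins in GFPlo were −0.18 as the mean of cells, thymocyte markers in GFPhi 0.014 as the Mantel-Haenszel ratio and −0.53 to 0.036 with each pool left out, and stress genes in GFPhi −0.015 without top cells.

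Among genes the direction turned with umi primers for Fezf2 (1.65), Epcam (−0.88) and Sirt1 (−0.62) in GFPhi, Cd79a in GFPlo (−0.34), S100a8 between gates in WT (−0.57) and Lyz2 in KO (2.18). With ls primers it turned for Insm2 (0.12) and Krtdap (0.14) between gates in WT. Without leukocyte-marked cells it turned for Epcam in GFPhi (−0.12) and Lyz2 between gates in KO (0.63). B2m in GFPhi was 0.0015 with TMM scaling, 0.056 without top cells and −0.20 to 0.066 with each pool left out, and Fezf2 in GFPlo was −0.089 to 0.83. The cause was not tested for these turns.

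For 66 results of lists (1 list in 1 comparison), values of a sort date lay outside the interval in 112 cases and within it in 19, and for 139 results of named genes in 96 and 166.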

Other observations

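The test below was chosen before its result was seen.

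Neighbouring rare genes were found in the same cells somewhat more often than by chance in WT GFPhi cells. Over 4299 pairs of neighbours 10 to 100 kb apart among 7528 rare genes, co-detection was 1.22 times its expectation, against 0.915 to 1.21 (median 1.05) in 1000 shuffles of gene positions. It was 1.18 in WT GFPlo (highest shuffle 1.24), 1.02 in KO GFPhi (1.26) and 1.27 in KO GFPlo cells (1.31). Leukocyte-marked cells, 22 of 61 in WT GFPhi before thinning, were not left out. The co-detection can thus not be told apart from the effect of a mix of cell types. Shared activation of neighbouring genes in single cells is a possible explanation, while differences between groups were not tested and the margin over the shuffles was small. Cells of known animals, sorted on more dates, could settle it.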
